A study of Homo sapiens with 74 samples.

How the data were processed

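The series held 74 samples of the human cell line HEK293T: 54 single cells and 4 bulk libraries in a table of 100 kb bins, 8 bulk libraries of a comparison of Dam variants and 8 RNA libraries. Samples were grouped by their labels, and replicate numbers were taken from the labels where these gave one. Per the labels, cells were transiently transfected with FuGene HD and treated with Shield-1, single cells were processed in a microfluidic device, and their libraries were made with the NEBNext Ultra II kit in batch 1 and its FS version in batch 2. The submitters' processing notes name Trimmomatic 0.39, BWA 0.7.15-r1140, SAMtools 1.9, bedtools 2.28, DESeq2, Salmon and limma, and the genome build hg38, without saying which tool was used for which file. Which aligner settings were used is not given in the sources used here.

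The values started from were of these kinds. For single cells, the authors deposited whole-number counts of unique fragments per 100 kb bin, deduplicated and not scaled per the file headers. For the 4 bulk libraries, the same deposited table holds whole-number coverage counts per bin; whether 1 unit is a read, a pair or a fragment is not given in the sources used here. That table also holds the authors' log2 fold change per bin and the authors' marks (0 or 1, coded as other than a measurement) of control LAD and iLAD bins. For the Dam variants, the authors deposited raw counts per DpnI fragment, 7180359 fragments with a median length of 263 bp. For RNA, the authors deposited estimated counts per gene, which are not whole numbers, with Ensembl GRCh38.p13 identifiers and symbols per the file headers; they were rounded before testing. Every value column was matched to 1 sample by name, and 0 pairs of columns held identical values.

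The 100 kb table covers 28163 bins of chromosomes 1 to 22. Fragments of the variant table were summed to 29160 bins of chromosomes 1 to 22 and X by position, which left out 0.0201% of the counts. RNA covered 39037 genes. Counts were tested with edgeR 4.0.16 in R 4.3.3, with the low-count filter filterByExpr, TMM scaling, glmQLFit and glmQLFTest, and Benjamini-Hochberg adjusted p under 0.05 as the threshold. The bulk test used 4 libraries. The variant and RNA tests used 1 fit each over 8 libraries in 4 groups, which share an estimate of the spread. A bin called higher in bulk DamV133A-LMNB1 over DamV133A is a LAD bin, a bin called lower an iLAD bin. The fitted log2 fold changes correlated with those of the authors' deposited table across bins at r = 0.99999 and differed from them by a median of 0.05. DESeq2 1.42.0 and limma 3.58.1 were used for alternatives and set tests, and Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 for the rest.

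For each variant library, the LAD contrast is the log2 ratio of counts per bin in LAD over iLAD bins, compared with an exact permutation test. For each cell, expected counts were set by the summed bulk DamV133A libraries, so that the contrast is 0 for a cell that follows them, and the share of fragments in LAD bins was given an exact Clopper-Pearson 95% interval. The area under the curve used observed over expected per bin. A bin was counted as contacted at observed over expected of 1 or more, with 2 as the alternative. Cells are not replicates, so medians and ranges are given without p-values. At a median of 94331 fragments in batch 1 cells and 110236 in batch 2 cells, a single bin of a single cell holds few fragments and carries little weight, so values are given over bins or over cells.

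Genes were placed by the midpoint of their span in the RefSeq table (GRCh38.p14), since that table gives no strand. They were kept by chromosome name alone, without a check that the coordinates were on the primary sequence of hg38. Some may therefore be misplaced, such as TAS2R45, at 300001 to 400000 of chromosome 12 against 10800001 to 10900000 for TAS2R10. The table holds 19126 autosomal protein-coding genes, 49 of which had no tested bin. Of them, 18181 (95.1%) were matched to an RNA gene by symbol, synonym or identifier. RNA levels are CPM, counts scaled to a common library size. Levels of named genes are after TMM scaling. Shares and medians by bin class, and the split of LAD genes by expression, used library totals alone. Gene lists were tested with camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over 68 tests, with camera's estimated correlation and fry as alternatives. The 15 gene lists, 18 gene families, groups, tests and most alternatives were fixed before the data were examined. Named genes were LMNB1, the 8 genes with the smallest adjusted p in each direction, and up to 4 called members per list with the largest absolute log2 fold change. Named regions were the 5 longest runs per direction, the 5 interaction bins with the smallest adjusted p per direction, and up to 4 family members in alphabetical order per class.

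The count tests were tried on simulated data for the bulk, wild-type variant and RNA fusion against DamV133A comparisons. Each of these simulations had 200 changed features drawn from the real means and library sizes. In the real data 19968 bulk bins, 755 wild-type variant bins and 3598 RNA genes were called. Recovery and false calls in the real tests may therefore differ from those below, most of all in bulk. The interaction, the other variant comparisons and the RNA comparisons with untreated cells were not simulated. For the bulk comparison (27888 bins), edgeR recovered 10.4%, 64.2% and 95.5% of changes of 0.5, 1 and 2 on the log2 scale with 9 false calls. For the wild-type variant comparison (28694 bins) it recovered 1.49%, 2.99% and 62.1% with 2 false calls, so that changes of up to 1 were mostly missed in this simulation. For RNA, fusion against DamV133A (17401 genes), it recovered 47.8%, 71.6% and 84.8% with 14 false calls. In the same RNA comparison camera called the planted list of 20 genes and 0 of 20 random lists. The simulated genes were drawn independently of each other. False calls for lists whose genes vary together were therefore not checked, and the real ribosomal list had an estimated correlation of 0.986. The single-cell contrast was recovered within 0.025 in 8 simulated cells.

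Alternatives were DESeq2's size factors, library totals alone, no low-count filter, the DESeq2 Wald test, the replicate number as a block, leaving out each library, bins of 500 kb, a minimum change of 1 on the log2 scale, thinning, other expected counts and other reference bins. Counts of covered fragments, the authors' control bins, library totals for RNA and placement by a gene's lowest coordinate were added after seeing the data. Raw reads, imaging and sex chromosomes of the single cells were not used here.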

Results

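DNA adenine methyltransferase identification (DamID) was used in HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen, to map DNA in contact with the nuclear lamina. The bacterial methylase Dam, which methylates the adenine of GATC, was expressed from transiently transfected plasmids, either alone or fused to lamin B1 (LMNB1), a structural protein of the lamina under the inner nuclear membrane. Methylated fragments were then released with DpnI and sequenced. Per the labels, the cells were given 1 mM of Shield-1, a ligand that stabilises proteins carrying a destabilised FKBP12 domain, for 20 hours. Dam was either wild type or the V133A variant, and m6A-Tracer, a protein that binds methylated GATC, was cotransfected in the single cells. The 74 samples fell into 13 groups. Bulk DamID had 2 libraries of DamV133A-LMNB1 and 2 of DamV133A, and a comparison of Dam variants had 2 libraries for each of 4 constructs. RNA sequencing had 2 libraries each of cells with DamV133A-LMNB1, with DamV133A, with m6A-Tracer and untreated. The 54 single cells were isolated in a microfluidic device: 15 cells with DamV133A-LMNB1 and 3 with DamV133A alone in batch 1, and 36 cells with DamV133A-tdTomato-LMNB1 in batch 2. Totals were 402171358 to 524019579 coverage counts in the bulk libraries, 3162041 to 10666805 counts in the variant libraries and 39690886 to 51455298 estimated counts in the RNA libraries. The single cells had 9526 to 348793 unique fragments. The labels do not say that replicates came from separate cultures, so the p-values below measure the spread between these samples, which may be technical.

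The first comparison asked which parts of the genome lay at the lamina, from bulk DamV133A-LMNB1 against untethered DamV133A. Of 27944 tested bins of 100 kb on chromosomes 1 to 22 (hg38), 9849 were higher with the fusion and are called lamina-associated domain (LAD) bins, with a median log2 fold change of 1.14. Another 10119 bins were lower and are called inter-LAD (iLAD) bins, with a median of -0.94, and 7976 passed in neither direction. Chromosome 4 had 63.3% of its bins in the LAD class and chromosomes 5 and 6 had 49.5% each. The gene-dense chromosomes 17, 22 and 19 had 4.69%, 1.57% and 0.535%. LAD bins held 2.20 protein-coding genes per Mb and iLAD bins 12.6 per Mb. The test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 20614 bins had an unadjusted p under 0.05. Library totals in place of TMM moved the median of all bins to -0.32 on the log2 scale and gave 8132 higher and 12448 lower bins. All 1185 bins that the authors' deposited table marks as control LADs were in the LAD class, and all 1200 marked control iLADs were in the iLAD class, from the same 4 libraries.

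**Figure D1:**
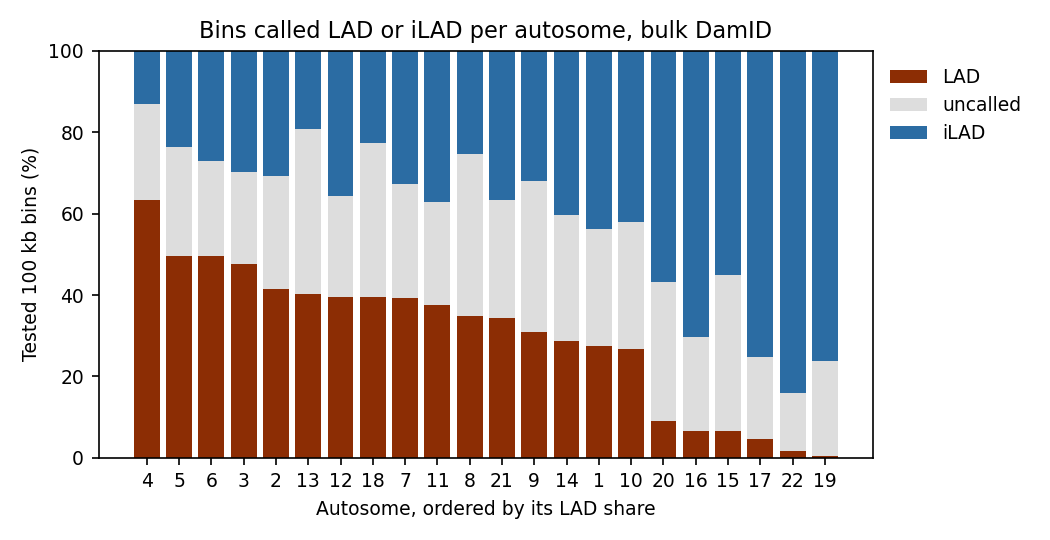
Percent of the tested 100 kb bins of each autosome that were higher with DamV133A-LMNB1 than with DamV133A (LAD), lower (iLAD) or called in neither direction, from 2 bulk libraries per group. Chromosome 4 has 63.3% of its bins in the LAD class, and chromosome 19 has 0.535%.

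The longest run of consecutive LAD bins spanned 13.7 Mb of chromosome 5 (17600001 to 31300000). It had a median log2 fold change of 1.47 and 12 protein-coding genes, among them CDH18, a cadherin of the nervous system. On chromosome 4, a run of 13.1 Mb (57500001 to 70600000) held 42 genes, among them the adhesion receptor gene ADGRL3, the ephrin receptor gene EPHA5 and CENPC, whose product binds centromeric chromatin. A second run on chromosome 4 of 9.9 Mb (128900001 to 138800000) had a median log2 fold change of 1.61 and 6 genes, including the protocadherins PCDH10 and PCDH18 and the cystine transporter SLC7A11. A run of 10.1 Mb on chromosome 7 (117300001 to 127400000) held CFTR, the chloride channel of epithelia, and the potassium channel gene KCND2. A run of 9.1 Mb on chromosome 12 (79900001 to 89000000) held the muscle regulatory factors MYF5 and MYF6. The longest iLAD run spanned 15.6 Mb of chromosome 22 (18400001 to 34000000) with a median log2 fold change of -1.12 and 191 genes, among them PRODH, which encodes proline dehydrogenase. The others lay on chromosome 1 (34800001 to 46900000, from the splicing factor gene SFPQ on), chromosome 12 (106600001 to 118200000, with the clock gene CRY1), chromosome 17 (200001 to 10500000) and chromosome 6 (29700001 to 38300000). The chromosome 6 run held HLA-F and HLA-G, class I genes of the major histocompatibility complex, and had 24.7 genes per Mb.

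Gene families differed in where their members lay. All 10 placed type 2 UDP-glucuronosyltransferase genes, whose enzymes conjugate steroids and drugs, lay in LAD bins, but they shared 8 bins. The bin of UGT2B10 (68800001 to 68900000) lay inside the 13.1 Mb run of chromosome 4 above. It had a log2 fold change of 1.68 ± 0.17 (SE, n = 2 and 2, edgeR adjusted p = 3.6e-08). Of 391 olfactory receptor genes, which shared 170 bins, 255 lay in LAD bins and 59 in iLAD bins, or 184 and 70 with library totals. Of 16 subunit genes of the GABA-A receptor, the main inhibitory neurotransmitter receptor of the brain, 9 lay in LAD bins and 4 in iLAD bins. Classical and desmosomal cadherin genes were split, with 16 of 30 in LAD bins, such as CDH10, CDH12 and CDH18, and 12 in iLAD bins, such as CDH13, CDH15 and CDH1, which encodes E-cadherin of epithelial junctions (-1.19 ± 0.21, edgeR adjusted p = 4.8e-05). The clustered protocadherins had 52 of 53 members in LAD bins, but these shared 7 bins and with library totals alone 1 member was left in a LAD bin and 1 lay in an iLAD bin. Of 25 bitter taste receptor genes, 9 were in LAD and 5 in iLAD bins, a balance that turned to 3 and 5 with library totals. TAS2R45, among those in iLAD bins, may be misplaced. In the other direction, 71 of 74 histone genes, 62 of 75 cytosolic ribosomal protein genes, 36 of 39 proteasome genes and all 22 PSG and CEACAM genes lay in iLAD bins. The histone genes shared 15 bins, and the PSG and CEACAM genes shared 15. Of the ribosomal protein and proteasome genes, RPL10L, a ribosomal protein retrogene used in the testis, and PSMD14, a proteasome deubiquitinase, lay in LAD bins, and with library totals no proteasome gene did. Of 505 zinc finger genes of the ZNF series 330 lay in iLAD bins and 18 in LAD bins, or 406 and 11 with library totals, next to 66.7% and 11.3% of all placed genes. No HOX gene lay in a LAD bin and 23 of 39 lay in iLAD bins, or 39 with library totals, and the HOX genes shared 9 bins.

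Fewer genes of LAD bins than of iLAD bins had RNA in the same line. In untreated cells 41.6% ± 0.07 (SD, n = 2) of 2082 protein-coding genes in LAD bins reached 1 CPM, the count scaled to a common library size, against 73.6% ± 0.06 of 12164 genes in iLAD bins and 64.4% ± 0.09 of 3919 in uncalled bins. Among genes that reached it, the median level was 15.5 CPM in LAD bins and 38.4 CPM in iLAD bins. The libraries of the 4 RNA groups spanned 41.1% to 42.3% for LAD bins and 73.5% to 74.7% for iLAD bins. No test was made across genes, which are not replicates, and at 0.1 CPM the untreated shares were 62.2% and 84.8%.

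The next comparison set the V133A variant of Dam against the wild-type enzyme, in 8 bulk libraries counted per DpnI fragment. The question was how much each variant raised signal in LADs over iLADs when tethered. Counts per bin in LAD over iLAD bins stood at a log2 value of 0.35 ± 0.009 (SD, n = 2) for wild-type Dam and 1.52 ± 0.025 for its LMNB1 fusion, a rise of 1.17, or 2.25-fold. For V133A the values were 0.08 ± 0.008 without and 2.83 ± 0.108 with LMNB1, a rise of 2.75, or 6.72-fold. The rise with V133A exceeded that with wild-type Dam by 1.58 ± 0.11 (SD of the difference), which is 2.99-fold. With covered fragments in place of counts the rises were 0.65 with wild-type Dam and 1.88 with V133A, and with the authors' control bins 1.54 and 3.73, both alternatives added after seeing the data. An exact two-sided permutation test gave p = 0.0556, the smallest that the 36 arrangements of these libraries allow. The LAD and iLAD classes came from libraries made with V133A, not with wild-type Dam.

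**Figure D2:**
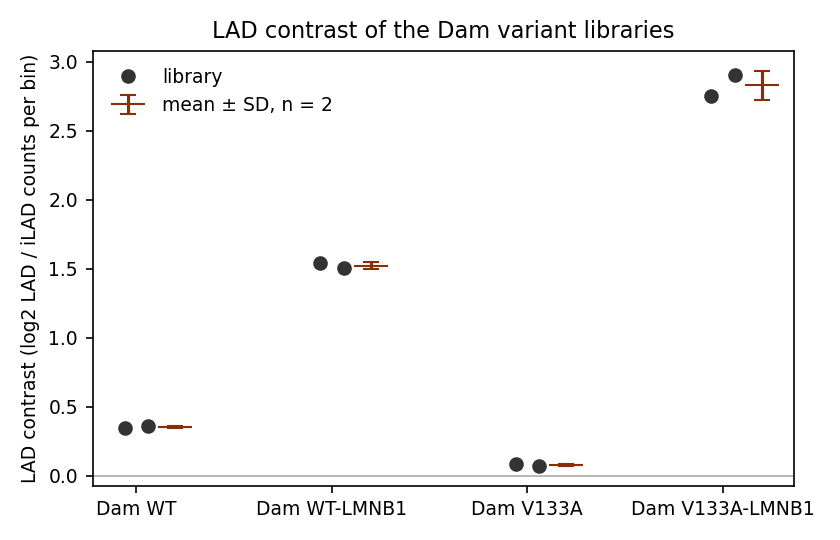
Log2 ratio of counts per bin in LAD over iLAD bins for each of the 8 libraries of the Dam variant comparison, with the mean and SD of each group (n = 2). The V133A fusion lies highest at 2.83, and V133A alone lies lowest at 0.08.

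Per bin, DamV133A-LMNB1 was higher than DamV133A in 7768 of 28733 bins on chromosomes 1 to 22 and X, and lower in 6797. Of these, 7238 higher bins lay in the LAD class and 5773 lower bins in the iLAD class. With wild-type Dam, 694 bins were higher with the fusion, 654 of them in the LAD class, and 61 were lower, 44 of them in the iLAD class. The median log2 fold change in LAD bins was 0.63 with wild-type Dam and 1.32 with V133A, and in iLAD bins it was -0.58 and -1.64. These calls are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 8 libraries in 1 fit. With library totals alone the V133A calls were 5317 higher and 9570 lower, with a median of all bins of -0.50, and the wild-type calls were 31 and 22. The DESeq2 test called 17426 bins with V133A and 4023 with wild-type Dam. The number of wild-type calls changed with the libraries used, although the rise in LAD over iLAD bins stayed at 1.15 to 1.19: 1 bin was called without wild-type Dam library 1, 0 without its library 2, 0 without fusion library 1 and 2669 without fusion library 2, and the V133A calls fell to 8869 and 9134 bins without the first or second DamV133A library. Wild-type fusion library 1 had 441781 covered fragments at 24.1 counts each, and its replicate had 847765 at 5.81. Both V133A fusion libraries were also low in covered fragments, with 481922 at 19.5 counts each and 481527 at 18.7. The libraries without LMNB1 had 780052 to 980277 at 3.23 to 10.2 counts each.

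The interaction, a direct test of whether the effect of the LMNB1 fusion differed between the variants, called 142 bins. The 39 with a higher effect under V133A all lay in the LAD class, and of the 103 with a lower effect 98 lay in the iLAD class. One of the former was on chromosome 6 (126400001 to 126500000), a bin with CENPW, which encodes a centromere protein, where the fusion's log2 fold change was 0.68 with wild-type Dam and 2.38 with V133A (interaction 1.71 ± 0.30 SE, edgeR adjusted p = 0.0449). One of the latter, on the same chromosome (31000001 to 31100000), held the mucin gene MUC22 and had -0.20 and -6.13 (interaction -5.93 ± 0.85, edgeR adjusted p = 0.0449). Another held BNIP3, a mitophagy receptor gene, and PPP2R2D on chromosome 10 (131900001 to 132000000), with -0.01 and -5.84. The split of 39 and 103 became 116 and 121 with DESeq2 size factors, 19 and 233 with library totals, 2468 and 1893 with the DESeq2 test, and 513 and 437 with covered fragments, an alternative added after seeing the data. With the replicate number as a block 0 bins were called, though these numbers only name the libraries. No bin was called without DamV133A library 1 or 2, wild-type Dam library 1 or 2, or wild-type fusion library 1; without wild-type fusion library 2 there were 859, and without V133A fusion library 1 or 2 there were 2509 and 2276. Without LMNB1, V133A and wild-type Dam differed in 0 of 28733 bins by edgeR, with 1447 at an unadjusted p under 0.05 and 177 called by DESeq2. Taken over many bins they were not alike: the median log2 fold change of V133A over wild-type Dam was -0.14 in LAD bins and 0.17 in iLAD bins. The log2 LAD over iLAD value of V133A minus that of wild-type Dam was -0.27 ± 0.012 (SD of the difference). This shift is part of the 1.58 by which the rise with V133A exceeded that with wild-type Dam.

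Single cells were then compared with the bulk map. In 15 batch 1 cells with DamV133A-LMNB1, the log2 ratio of observed over expected fragments in LAD bins to that in iLAD bins had a median of 2.43 (range 0.43 to 3.68), a 5.38-fold contrast. Expected counts came from the summed bulk DamV133A libraries. The 3 cells with DamV133A alone had -0.27, -0.75 and -1.45, and the summed bulk LMNB1 libraries had 2.08. All 15 cells lay above the highest Dam-only cell, and 10 lay above the bulk value. LAD bins took a median of 80.5% of the fragments in either class in the LMNB1 cells and 31.2% in the Dam-only cells, against 43.4% in bulk Dam and 76.3% in bulk LMNB1. The highest cell had 90.7% (exact Clopper-Pearson 95% interval 90.6 to 90.9) and the lowest 50.7% (50.5 to 50.9), intervals that cover counting error only. The 36 batch 2 cells had a median log2 contrast of 1.64 (range -0.01 to 3.31), or 3.13-fold, and all lay above the highest Dam-only cell of batch 1. Batch 2 differed in construct, tracer and library kit together, and its Dam-only background was not analysed here. The labels tie no cell to a culture, so each group counts as 1 sample and no p-value is given.

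**Figure D3:**
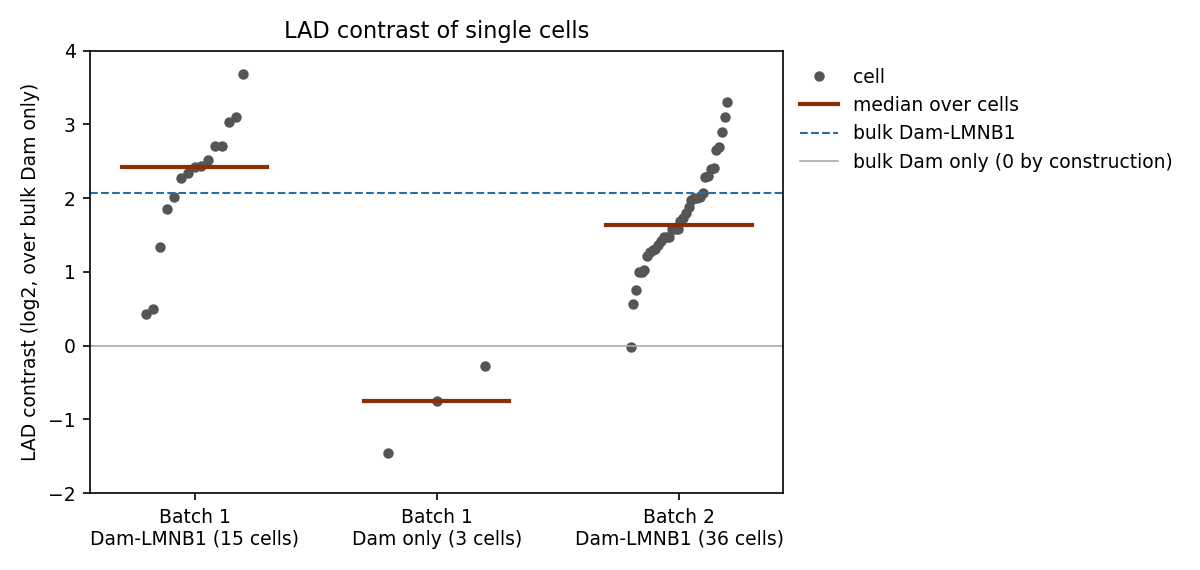
Log2 ratio of observed over expected fragments in LAD bins to that in iLAD bins for each of 54 cells, sorted by value within each group, with group medians as lines and the summed bulk LMNB1 libraries at 2.08 as a dashed line. All cells with an LMNB1 fusion lie above the highest of the 3 Dam-only cells at -0.27.

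A few cells with the fusion had little contrast. In batch 1, cells 7 and 12 were at 0.43 and 0.50, and in batch 2, cells 34, 35 and 36 were at 0.75, -0.01 and 0.56. The area under the receiver operating characteristic curve for telling LAD from iLAD bins within a cell had medians of 0.769 in batch 1, 0.377 in the Dam-only cells and 0.810 in batch 2. Thinned to 10000 fragments, these were 0.649, 0.428 and 0.617, with the batches in the opposite order. The thinned values leave out the 1 batch 1 LMNB1 cell with under 10000 fragments.

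A bin was counted as contacted in a cell when its fragments reached the expected number. LAD bins were contacted on average in 59.8% of the batch 1 LMNB1 cells and 62.3% of the batch 2 cells, and iLAD bins in 14.3% and 17.2%. In the Dam-only cells the order was the other way, 28.1% for LAD and 48.5% for iLAD bins. Of the LAD bins, 13.9% were in contact in at least 80% of the cells in batch 1 and 12.0% in batch 2. These shares depended on depth: thinned to 10000 fragments per cell, contact of LAD bins was 38.4% and 36.8% and that of iLAD bins 13.4% and 16.7%. The thinned shares leave out the batch 1 cell with 9504 fragments. Before thinning, the batch 1 cells with 9504 and 15320 fragments had 18.9% and 26.5% of LAD bins in contact. The run on chromosome 5 with CDH18 was contacted in 69.9% of batch 1 and 65.8% of batch 2 cells per bin, and the gene-rich run on chromosome 6 with HLA-F and HLA-G in 12.2% and 8.88%. The bins of the type 2 UDP-glucuronosyltransferase genes were contacted in 68.3% and 71.9% of cells, those of olfactory receptors in 46.5% and 53.0%, those of histone genes in 8.44% and 14.8% and those of proteasome genes in 10.8% and 11.0%. Dam-only cells had 25.0%, 34.3%, 64.4% and 50.5% for these 4 families. With a contact set at 2 times the expected number, LAD and iLAD bins stood at 37.0% and 4.85% in batch 1 and at 33.6% and 5.33% in batch 2.

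**Figure D4:**
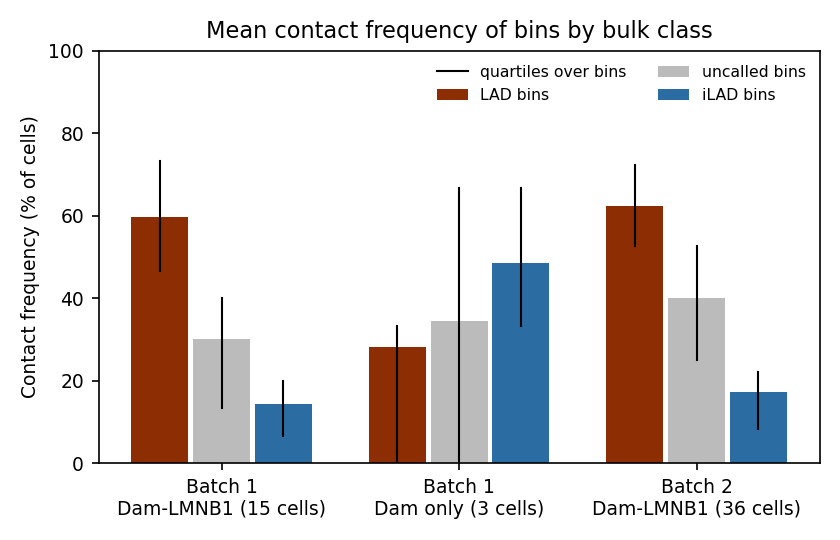
Mean percent of cells in contact per 100 kb bin, by bin class, for the 15 batch 1 LMNB1 cells, 3 Dam-only cells and 36 batch 2 cells, with lines for the quartiles over bins. LAD bins reach 59.8% and 62.3% in the LMNB1 cells and 28.1% in the Dam-only cells.

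Across bins, contact frequency followed the bulk log2 fold change with r = 0.79 in batch 1 and 0.75 in batch 2, and the batches followed each other with r = 0.81. Within LAD bins the first 2 values were 0.49 and 0.39. Bins are not independent replicates, so no p-value is given. Contact and the bulk log2 fold change both use the bulk DamV133A libraries as the reference, and the batches share the same expected counts. How much of these correlations comes from the shared reference was not tested.

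RNA was compared between cells with the constructs and untreated cells, and between fusion and DamV133A. If untreated cells had neither transfection nor Shield-1, comparisons with them cannot separate a construct from these treatments. The p53 and hypoxia lists below moved the same way with m6A-Tracer, whose label names no Dam. DamV133A was not compared with m6A-Tracer. LMNB1, whose coding sequence the fusion carries, stood at 2556 and 2058 CPM in the 2 fusion libraries and at 248 and 253 CPM with DamV133A alone (log2 fold change 3.19 ± 0.09 SE, edgeR adjusted p = 1.1e-05). It was also higher in untreated cells, at 767 and 770 CPM, than with m6A-Tracer, at 250 and 257 CPM (log2 fold change -1.59 ± 0.09 for m6A-Tracer, edgeR adjusted p = 0.000191). FKBP1A, the gene of FKBP12, stood at 628 and 585 CPM with the fusion, 848 and 844 with DamV133A, 290 and 284 with m6A-Tracer and 359 and 357 in untreated cells. Counts cannot separate the native genes from construct RNA with the same coding sequence.

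Between fusion and DamV133A, all 24 measured ribosomal protein genes rose with the fusion, with a median log2 fold change of 0.51, for example RPS19 (0.72 ± 0.12 SE) and RPLP1 (0.69 ± 0.10). Hypoxia and glycolysis genes rose in 10 of 17 cases and fell in 0 (12 and 0 adjusted over the list alone), among them PGK1 (0.46 ± 0.06), a glycolytic kinase, and BNIP3 (0.42 ± 0.07). Of 24 genes of the unfolded protein and integrated stress response 11 rose and 0 fell (16 and 2 adjusted over the list alone), including the mTOR inhibitor DDIT4 (0.53 ± 0.06) and the chaperone cofactor SDF2L1 (0.54 ± 0.12). Of 20 p53 targets 5 fell and 1 rose (6 and 2 adjusted over the list alone): MDM2, the ubiquitin ligase of p53, fell (-0.35 ± 0.05) and BBC3, the apoptotic factor PUMA, rose (0.36 ± 0.10). Of 20 mitosis genes 4 fell and 2 rose (6 and 4 adjusted over the list alone), among them MKI67 (-0.88 ± 0.25) and CENPE (-0.64 ± 0.14), and 7 of 20 DNA replication genes rose and 1 fell (7 and 2 adjusted over the list alone), with PCNA, the sliding clamp, at 0.31 ± 0.07. The 2 fusion libraries differed in MKI67, with 318 and 159 CPM against 430 and 444 with DamV133A and 311 and 319 in untreated cells. Of 18 immediate early genes 2 rose and 1 fell, both over all genes and adjusted over the list alone, with EGR1 at -0.51 ± 0.06. Of 18 lamina genes 2 rose and 2 fell (5 and 5 adjusted over the list alone): besides LMNB1, BANF1, a chromatin tether, rose (0.53 ± 0.10), and SYNE2 (-0.77 ± 0.20), a nesprin, and TPR (-0.57 ± 0.17), a nuclear pore protein, fell. Fusion library 2 had the lower level of both, 31.5 against 53.2 CPM for SYNE2 and 263 against 410 CPM for TPR, and the higher level of RPS19, 1233 against 907 CPM. It was also lower in CENPE (87.0 against 124 CPM) and higher in PCNA (372 against 316) and SDF2L1 (90.0 against 66.9). The 2 fusion libraries were close in DFFA (191 and 187 CPM), MDM2 (123 and 121) and EGR1 (36.3 and 34.5). How far the changes between fusion and DamV133A follow this difference between libraries was not tested. Single genes with the smallest p included DPH1 (0.58 ± 0.06), of diphthamide synthesis, DFFA (0.43 ± 0.05), the inhibitor of the apoptotic DNase, and TSC22D3 (0.53 ± 0.06), the glucocorticoid-induced leucine zipper gene, and, lower, SEC31B (-0.81 ± 0.08), GIGYF1 (-0.56 ± 0.05) and TTLL3 (-0.67 ± 0.08), each with an edgeR adjusted p = 0.018.

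In that comparison 2258 of 17740 genes were higher and 1340 lower by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 144 of them changed at least 2-fold. Library totals gave 1458 higher and 2363 lower. The calls needed both DamV133A libraries: 1 gene was called without either of them, with 0 of 24 ribosomal protein and 0 hypoxia genes called, against 8956 genes without fusion library 1. The camera test with a preset correlation of 0.01 called the ribosomal (adjusted p = 7.5e-12), hypoxia (adjusted p = 3.3e-05), stress response (adjusted p = 4.9e-05) and cholesterol (adjusted p = 0.0355) lists higher. None held with an estimated correlation (adjusted p = 0.487, 0.226, 0.474 and 0.274). Genes in LAD bins were not called as a list (camera adjusted p = 0.0775). Ribosomal protein genes share reads with many processed pseudogenes, so their counts are uncertain.

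**Figure D5:**
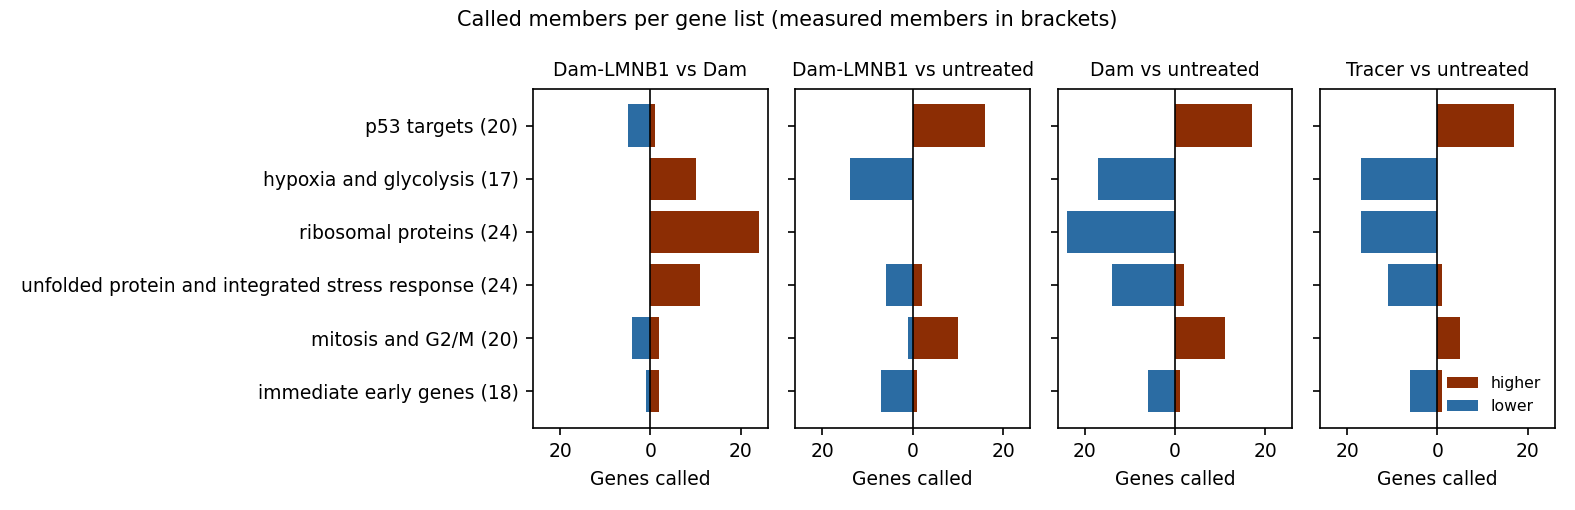
Number of genes of 6 fixed lists called higher or lower by edgeR in each of the 4 RNA comparisons, with 2 libraries per group. All 24 ribosomal protein genes are higher with the fusion than with DamV133A and lower with DamV133A than in untreated cells.

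Against untreated cells, p53 targets rose with the fusion: 16 of 20 rose and 0 fell (17 and 0 adjusted over the list alone), with a median log2 fold change of 0.53. They included PLK3 (1.48 ± 0.11 SE), a stress kinase, the exonuclease gene AEN (1.32 ± 0.06), DDB2 (1.17 ± 0.10), of nucleotide excision repair, and PHLDA3 (1.09 ± 0.09), an inhibitor of AKT. Hypoxia and glycolysis genes fell in 14 of 17 cases and rose in 0 (16 and 0 adjusted over the list alone), among them the glucose transporter SLC2A3 (-1.42 ± 0.09), NDRG1 (-0.82 ± 0.05) and the hexokinase HK2 (-0.76 ± 0.07). Outside that list BHLHE40 (-0.94 ± 0.05) and HILPDA (-0.88 ± 0.07), both known hypoxia-inducible genes, fell as well. LIF, a cytokine gene, rose from 1.94 ± 0.14 CPM (SD, n = 2) to 10.9 CPM (log2 fold change 2.48 ± 0.11, edgeR adjusted p = 6.1e-05), and RASSF1, a tumour suppressor gene, rose too (1.51 ± 0.06). HIST2H4A, a histone H4 gene with an identical copy and so uncertain, had 2.44 ± 0.08, while HOXA13, a homeobox gene, fell (-1.16 ± 0.08). Of 20 mitosis genes 10 rose and 1 fell (11 and 2 adjusted over the list alone), for example BIRC5 (0.58 ± 0.07) and CDC20 (0.49 ± 0.07), and 4 of 20 DNA replication genes rose and 0 fell (5 and 0 adjusted over the list alone), with MCM5 at 0.41 ± 0.05. Of 18 immediate early genes 7 fell and 1 rose (7 and 2 adjusted over the list alone): FOS (-0.75 ± 0.08) and ARC (-0.81 ± 0.10) fell and FOSL1 rose (0.99 ± 0.13). The endoplasmic chaperone HSPA5 fell (-0.52 ± 0.04), with 2 of its stress list's 24 genes higher and 6 lower (3 and 7 adjusted over the list alone), and of 18 lamina genes 4 rose, including LMNA (0.41 ± 0.08), and 3 fell (4 and 4 adjusted over the list alone).

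This comparison called 2019 genes higher and 1342 lower of 17740 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment), 265 of them at least 2-fold. Leaving out untreated library 1 or 2 gave 522 and 590 genes, with 9 and 10 p53 targets higher and 11 hypoxia genes lower in each, and leaving out fusion library 1 or 2 gave 8415 and 5345, with 18 p53 targets in each and 13 and 17 hypoxia genes. The ribosomal list had 0 genes called by edgeR in either direction, also adjusted over the list alone, with 0 at an unadjusted p under 0.05 and 0 by DESeq2, but 18 rose without fusion library 1 and 23 fell without fusion library 2; in these 2 fits only 1 fusion library is left. The preset camera test called p53 targets (adjusted p = 3.5e-11), hypoxia (adjusted p = 3.1e-11), mitosis (adjusted p = 0.0105), immediate early genes (adjusted p = 0.0268) and, as lower, the 1216 measured genes of LAD bins (adjusted p = 0.0416). These calls were lost with an estimated correlation (adjusted p = 0.0867, 0.105, 0.203, 0.228 and 0.826).

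With DamV133A alone against untreated cells, 17 of 20 p53 targets rose and 0 fell (18 and 0 adjusted over the list alone), with a median log2 fold change of 0.65. PLK3 (1.51 ± 0.11 SE), AEN (1.37 ± 0.06), DDB2 (1.27 ± 0.10) and PPM1D (1.06 ± 0.06), a phosphatase that acts back on p53, had the largest changes. All 17 hypoxia and glycolysis genes fell, with a median of -0.76, among them SLC2A3 (-1.66 ± 0.09), NDRG1 (-1.03 ± 0.05) and BNIP3 (-0.95 ± 0.07), and so did HILPDA (-1.37 ± 0.07) and BHLHE40 (-1.19 ± 0.05). LIF rose to 17.0 CPM (3.13 ± 0.11, edgeR adjusted p = 1.7e-05), FKBP1A by 1.25 ± 0.05 and RASSF1 by 1.33 ± 0.06. All 24 ribosomal protein genes fell, with a median of -0.54, for example RPS18 (-0.67 ± 0.09) and RPL7A (-0.66 ± 0.09). In the stress response list 14 genes fell and 2 rose (15 and 2 adjusted over the list alone), among them DDIT4 (-1.04 ± 0.06) and HSPA5 (-0.60 ± 0.04). Of 20 mitosis genes 11 rose and 0 fell (14 and 0 adjusted over the list alone), such as AURKA (0.43 ± 0.06) and TPX2 (0.42 ± 0.05). Of 18 immediate early genes 6 fell and 1 rose (7 and 1 adjusted over the list alone), with JUNB at -0.70 ± 0.07 and FOSL1 at 1.21 ± 0.13. Of 20 DNA replication genes 4 rose and 2 fell, as they did adjusted over the list alone, with CDC6 at 0.45 ± 0.05, and of 18 lamina genes 2 rose and 2 fell in both adjustments, LMNB1 with the largest change (-1.61 ± 0.09).

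Here 2408 genes were higher and 2322 lower of 17740 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment), 481 of them at least 2-fold, and library totals gave 3470 and 1419, with a median of all genes of 0.10. Without DamV133A library 1 or 2 the calls numbered 1586 and 1389, and without untreated library 1 or 2 they numbered 1437 and 1697, with 13 to 15 p53 targets higher and 16 to 17 hypoxia genes and 11 to 20 ribosomal protein genes lower in these fits. The preset camera test called p53 targets (adjusted p = 1.2e-10), hypoxia (adjusted p = 1.5e-13), ribosomal proteins (adjusted p = 3.5e-11), the stress response (adjusted p = 0.000269) and mitosis (adjusted p = 0.000327). With an estimated correlation none was called (adjusted p = 0.0867, 0.0867, 0.508, 0.487 and 0.118).

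In cells with m6A-Tracer p53 targets rose against untreated cells: 17 of 20 rose and 0 fell (18 and 0 adjusted over the list alone), with a median log2 fold change of 0.48, including PLK3 (1.42 ± 0.11 SE), AEN (1.17 ± 0.06) and PPM1D (0.87 ± 0.06). All 17 hypoxia and glycolysis genes fell, among them SLC2A3 (-1.38 ± 0.09) and P4HA1 (-0.72 ± 0.05), a collagen prolyl hydroxylase. LIF rose to 14.9 CPM (2.94 ± 0.11, edgeR adjusted p = 4.1e-05), and PLK2 (1.84 ± 0.10), a kinase related to PLK3, and DHRS2 (1.89 ± 0.11), a short-chain dehydrogenase gene, rose too. Of the ribosomal protein genes 17 of 24 fell and 0 rose (24 and 0 adjusted over the list alone), with RPL7A at -0.49 ± 0.09, and of the stress response genes 11 of 24 fell and 1 rose (14 and 2 adjusted over the list alone), with HERPUD1, of endoplasmic reticulum degradation, at -0.48 ± 0.06. Of the 20 mitosis genes 5 rose and 0 fell (8 and 0 adjusted over the list alone), with AURKA at 0.37 ± 0.06, and of the 20 DNA replication genes 2 rose and 1 fell (3 and 1 adjusted over the list alone), with CDC6 at 0.28 ± 0.05. Of 18 immediate early genes 6 fell and 1 rose in both adjustments, with FOS at -0.68 ± 0.08, and of 18 lamina genes 2 rose and 1, LMNB1, fell in both adjustments.

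With m6A-Tracer 1352 genes were higher and 829 lower of 17740 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment), 264 of them at least 2-fold. Library totals gave 2001 and 501. Without m6A-Tracer library 1 or 2 the calls numbered 308 and 374, and without untreated library 1 or 2 they numbered 310 and 311; no ribosomal protein gene, 7 to 8 p53 targets and 10 to 11 hypoxia genes were called in these fits. The preset camera test called p53 targets (adjusted p = 5e-11), hypoxia (adjusted p = 3.3e-15), ribosomal proteins (adjusted p = 3.5e-10), the stress response (adjusted p = 8.6e-05), mitosis (adjusted p = 0.00136) and immediate early genes (adjusted p = 0.0221). With an estimated correlation none was called (adjusted p = 0.0867, 0.0867, 0.543, 0.474, 0.144 and 0.226). The 3 comparisons with untreated cells share the same 2 untreated libraries and so share their chance values.

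Markers of other cell types were looked at beside these lists. The neuronal vesicle gene SNAP25 was higher than in untreated cells with the fusion (3.33 ± 0.34 SE), DamV133A (3.37 ± 0.34) and m6A-Tracer (2.94 ± 0.35), at 1.2 to 1.6 CPM, while the neurofilament gene NEFL was lower in the same comparisons (-0.58, -0.89 and -0.65; all by the edgeR test). PDGFRB, a platelet-derived growth factor receptor gene among the 7 fibroblast markers, was higher (1.48, 2.64 and 2.58), and PDGFRA was lower with the fusion (-1.16 ± 0.25); no other fibroblast marker was called against untreated cells over all genes, and 1 more fell with DamV133A adjusted over the list alone. Of 9 neuron markers 2 rose and 2 fell with the fusion, 1 rose and 2 fell with DamV133A, and 1 rose and 2 fell with m6A-Tracer, against 3 and 3, 2 and 3, and 1 and 3 adjusted over the list alone. Of 5 blood markers CD14 (1.55 ± 0.43) rose with DamV133A, and 0 were called in the other comparisons. Between fusion and DamV133A, the neuron markers SYP (0.37 ± 0.08) and NEFL (0.31 ± 0.05) were higher and PDGFRB (-1.16 ± 0.28) was lower, with the same counts adjusted over the list alone.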

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

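The tests of explanations for the LMNB1 level in untreated cells and for the cells of low contrast were chosen only after the result was seen, and those for the ribosomal protein genes before it.

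The test of the difference between Dam variants picked out 142 bins in which the effect of the LMNB1 fusion differed, and 0 without DamV133A library 1 or 2, wild-type Dam library 1 or 2, or wild-type fusion library 1. The interaction was higher under V133A by 1.65 and 1.62 (log2) at chromosome 13, 90400001 to 90500000 and 71100001 to 71200000, by 2.56 at chromosome 14, 43300001 to 43400000, by 1.71 at chromosome 6, 126400001 to 126500000, and by 2.17 at chromosome 5, 102300001 to 102400000. It was lower by the same test at chromosome 6, 31000001 to 31100000 (-5.93), chromosome X, 101100001 to 101200000 (-3.62), chromosome 17, 46100001 to 46200000 with KANSL1 (-3.25), chromosome 20, 38000001 to 38100000 with TTI1 and RPRD1B (-4.29), and chromosome 10, 131900001 to 132000000 (-5.82).

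LMNB1 RNA stood at 767 and 770 CPM in untreated cells, against 248 to 257 CPM with DamV133A or m6A-Tracer. Admixture of whole RNA of the fusion cells would need a share of at least 22.2%. It is argued against by 5 of 12880 genes examined, CTC-435M10.3, GDF15, HIST2H4A, NECTIN4 and XKR7. These lay under the level that share would bring in both untreated libraries (XKR7 0.16 and 0.37 CPM against 1.02). HIST2H4A has an identical copy, so its level is uncertain. A general fall of cell-cycle genes in transfected cells is argued against too, since the lowest of the 4 median log2 changes of the replication and mitosis lists was -0.00404. Sequence of the construct alone in the untreated libraries is a candidate explanation: FKBP1A was 70.9 CPM higher in them than with m6A-Tracer, close to the 80.01 CPM that its ratio to LMNB1 in the fusion libraries predicts, although 6.81% of 2423 abundant genes lay as far below untreated in that comparison. A native difference in LMNB1 between untreated and transfected cells was not tested and stays open.

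In cells 7 and 12 of batch 1 and 34, 35 and 36 of batch 2 the LAD contrast was under 1 despite the fusion. The tests used uncalled bins and compared, on the log2 scale, fragment density between the quartiles of bins richest and poorest in bulk Dam counts per GATC fragment, a value of 1.30, 1.32 and 1.71 in the Dam-only cells. In batch 1, evenly spread fragments not set by Dam, as the only source, are argued against by 0.89 in cell 12, and free Dam cannot be told apart from other sources because cell 7 reached 1.29 and cell 12 did not. In batch 2, the highest of the 3 cells had 0.39, which argues against free Dam alone, as in the batch 1 Dam-only cells, with the limit that a Dam-only cell of batch 2 was not analysed here. Evenly spread fragments stay open there, as the lowest cell had 0.21, and mixtures of either source with fusion methylation stay open in both batches, as the 46 other fusion cells ran from -0.13 to 1.57, so the measure separates the sources little; no biological explanation was tested, since the labels give no state of these cells.

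Ribosomal protein RNAs were lower with DamV133A and m6A-Tracer than in untreated cells, by medians of -0.54 and -0.37. TMM scaling as the source is argued against, since with library totals alone the medians were -0.44 and -0.30. A loss of short transcripts cannot be told apart from a change in these genes. The 295 other genes compared had a genomic span, introns included, of at most 22944 bp. Their RNA level was no lower than that of the lowest ribosomal protein gene. They had medians of -0.17 and -0.13, between the bounds set for that test. Span is not transcript length, so short transcripts as such were not tested. With m6A-Tracer, 0 of the 24 genes passed the test when any 1 of its 2 libraries or of the 2 untreated ones was left out. An effect of transfection on the cells, which the groups would allow, was not tested against these and stays open.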

How the results depend on the processing

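The alternatives with covered fragments, the authors' control bins, library totals for RNA and placement by lowest coordinate were chosen only after the result was seen; the others were planned. Of 2057 values of named RNA genes under the alternatives 1677 stayed past the threshold, 380 lost it and 0 turned, mostly where 1 library was left out. Of 68 tests, 17 lists in 4 comparisons, camera called 20, 0 of which were called with an estimated correlation, and fry 33, with 2 of the 20 lost and 15 gained.

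Bins of 500 kb called 4873 in bulk, 4701 for V133A, 2513 for wild-type Dam and 2605 for the interaction, all from fewer bins, 5648 in bulk and 5839 in the others. For wild-type Dam, library totals gave 53 and DESeq2 4023 bins. For the interaction, DESeq2 size factors gave 237, library totals 252, the DESeq2 test 4361 and covered fragments 950. For V133A against wild-type Dam alone, with 0 by edgeR and 1447 at an unadjusted p under 0.05, DESeq2 gave 177, 500 kb bins 70 and covered fragments 3. Without a low-count filter RNA gave 5437 genes for fusion against DamV133A and 3507 for m6A-Tracer. A minimum log2 change of 1 left 144, 265, 481 and 264 genes (fusion against DamV133A, then fusion, DamV133A and m6A-Tracer against untreated), by its construction. Apart from that and the bin number, the cause was not tested.

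The numbers of same-numbered libraries only name them: the correlations of their deviations ran from -0.050 to 0.031. With the replicate block the interaction called 0 bins, fusion against DamV133A 2077 genes and m6A-Tracer 1422; it moved the other counts by less than 1.5 times.

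The LAD contrasts of wild-type Dam, V133A and their difference were 1.37, 3.34 and 1.96 with reference bins changed by at least 1, 0.65, 1.88 and 1.23 with covered fragments, and 1.54, 3.73 and 2.18 with the authors' control bins. The single-cell medians were 2.73 and 3.33 in batch 1 and 2.01 and 2.45 in batch 2 with reference bins changed by at least 1 and with the authors' bins. The areas under the curve were 0.840 and 0.895 in batch 2 with these. Thinned to 10000 fragments they were 0.649 in batch 1, without its 1 cell under that number, 0.428 in Dam-only cells and 0.617 in batch 2. Batch 2 contact of LAD bins was 33.6% at a ratio of 2 and 36.8% thinned, and of iLAD bins 5.33% at a ratio of 2. The share of expressed genes was 62.2% (LAD) and 84.8% (iLAD) at 0.1 CPM and 41.5% (LAD) by lowest coordinate. The cause was not tested.

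Leaving out each library, where the lone one left is assumed to vary like the other groups, gave 15703 to 19710 bins in bulk, 0 to 2669 for wild-type Dam, 8869 to 14631 for V133A, 0 to 2509 for the interaction and 0 to 1 for the variants without LMNB1. RNA gave 1 to 8956 genes for fusion against DamV133A and 522 to 8415, 1389 to 1697 and 308 to 374 for fusion, DamV133A and m6A-Tracer against untreated. The LAD contrasts ran from 1.15 to 1.19, 2.67 to 2.82 and 1.503 to 1.66, and the Dam-only median from -1.10 to -0.51. The wild-type libraries held 3162041 to 10666805 counts. Not run were autosomes only for the LAD contrast, as the reference bins are all autosomal, and placement by transcription start, as no strand was used.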

Other observations

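The tests of gene lists below were planned; the split of LAD genes by expression was chosen after the result was seen.

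Genes of LAD bins were split by their RNA in untreated cells, without a test, since genes share bins and are not replicates. The 860 genes at 1 CPM or more lay in bins contacted in 49.2% of batch 1 and 52.1% of batch 2 LMNB1 cells, and the 1222 genes under 1 CPM in bins contacted in 57.8% and 61.2%. Dam-only cells had 32.9% and 29.4%. The bulk medians were 0.86 and 0.92 on the log2 scale. Of the smaller families, the bins of PSG and CEACAM genes, which encode placental and epithelial glycoproteins, were contacted in 14.7% and 22.2% of the LMNB1 cells and 71.1% of the Dam-only cells, and those of HOX genes in 11.1%, 12.7% and 51.9%. Keratin-associated protein genes lay in LAD bins in 24 and in iLAD bins in 61 of 94 cases, or 13 and 61 with library totals, beta-defensin genes in 4 and 25 of 39, complex I genes in 2 and 28 of 35, and chaperonin genes in 0 and 8 of 10. The first 2 families had 25.5% and 10.3% in LAD bins and 64.9% and 64.1% in iLAD bins. All placed genes had 11.3% and 66.7%, so neither family lay in iLAD bins more often than genes at large. The keratin-associated protein genes shared 18 bins, and the beta-defensin genes shared 18. Serpin B genes split 3 and 3 of 13, or 2 and 4 with library totals, and of 15 interferon genes IFNB1 alone lay in a LAD bin, or 0 with library totals. The interferon cluster on chromosome 9 stood at 36.0% and 55.0% in the LMNB1 cells.

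Few innate immune genes were called in the RNA. Of 27 interferon-stimulated genes, 2 rose and 0 fell with the fusion against untreated cells, 2 rose and 3 fell with DamV133A, and 1 rose and 1 fell with m6A-Tracer, by edgeR's adjusted p; adjusted over the list alone these were 1 and 0, 1 and 2, and 0 and 0. DDX58, the RNA sensor RIG-I, rose in these comparisons by 0.65, 0.86 and 0.53 on the log2 scale, while IFITM1 fell by 1.34 with DamV133A. Of 12 NF-kB targets 1, 2 and 0 rose and none fell (0, 2 and 0 adjusted over the list alone), among them BIRC3 with DamV133A (1.14 ± 0.31 SE). Between fusion and DamV133A, 3 interferon-stimulated genes rose, BST2 (2.11), IFITM1 (0.80) and USP18 (0.24), and none adjusted over the list alone, while 0 NF-kB targets were called in either adjustment. BST2 lay near the floor, at 0.42 and 0.88 CPM with the fusion, 0.12 and 0.17 with DamV133A and 0.550 and 0.565 in untreated cells. Heat shock genes gave 5 higher and 0 lower of 19 with the fusion, 6 and 5 with DamV133A and 4 and 1 with m6A-Tracer against untreated cells (5 and 0, 8 and 6, and 4 and 1 adjusted over the list alone), with the cochaperone BAG3 higher in each (0.32, 0.36 and 0.34), and 5 and 1 between fusion and DamV133A in both adjustments, with the small heat shock protein gene HSPB1 at 0.72. Cholesterol genes gave 4 higher and 3 lower of 20 with the fusion, 1 and 2 with DamV133A and 0 and 1 with m6A-Tracer, and 4 higher and 0 lower between fusion and DamV133A, the same adjusted over the list alone; INSIG1, a brake on sterol synthesis, fell by 0.45 with DamV133A and by 0.34 with m6A-Tracer.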
